A study of Homo sapiens with 4 samples.

How the data were processed

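A set of 4 RNA libraries of MDA-MB-231 cells, a triple-negative human breast cancer line, were used: 2 libraries of RNA recovered with an antibody against SF3B6 (IP) and 2 input libraries. The series design text calls the members of each pair biological replicates. Per the labels' protocols, cells were irradiated once at 400 mJ/cm2, the lysate was treated with DNase and then digested with micrococcal nuclease, and 5 ug of SF3B6 antibody was used for the pull-down. Per the same protocols, RNA was purified with phenol and chloroform after high-salt washes, and libraries were made with a KAPA RNA kit. The cell line entries of the samples differ in their last digit, while all 4 titles give MDA-MB-231, which was used. An IgG antibody is named in these protocols, but only input served as the reference here, so unspecific recovery is not separated from binding to SF3B6. The knockdown RNA-seq that the design text mentions is not analysed here.

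The authors deposited a table of read counts per gene, not normalized, and a table of FPKM values of the same genes. HISAT2, HOMER and the hg38 build are named in the submitters' processing notes, with no role or version given. The counter, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical gene copies, overlapping genes and antisense partners can therefore be split or counted together in ways that the tables do not show. FPKM values deposited by the authors are counts divided by gene length and by a library total, whose content is not given in the sources used here. That total was recovered here from counts, FPKM and RefSeq gene lengths over 14, 9, 36 and 40 genes of SF3B6 IP 1, SF3B6 IP 2, input 1 and input 2, using genes with at least 20 counts. In units of 1e+06 it came to 0.758, 0.501, 2.12 and 2.55.

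The table lists 18276 genes, of which 15134 symbols matched the RefSeq gene table of GRCh38.p14, the same build as the authors named, so that its coordinates are given. The symbols include 49 that occur more than once. Counts assigned to genes summed to 55492 and 30431 in SF3B6 IP 1 and 2, and to 317190 and 519836 in input 1 and 2. A count of 0 allowed up to 3 counts, which is 54.1, 98.6, 9.46 and 5.77 CPM (counts scaled to a library total of 1e+06) in these libraries. Wilson intervals at 95% were used for shares and exact intervals for count ratios. Without molecular identifiers such intervals and floors cover counting error only.

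The 2 IP libraries differed by more than sampling noise (chi-square over degrees of freedom 4.33 across 576 genes), as did the inputs (1.72 across 6053 genes), so each library was counted as 1 replicate. IP and input libraries have no common absolute scale, so every fold change is relative to the rest of the library.

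IP and input were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalization (factors 0.968, 0.860, 1.06 and 1.13), the default expression filter, group as the one term and Benjamini-Hochberg adjustment at 0.05. The filter kept 3668 genes. Normalised levels are CPM after TMM, given as mean ± SD over 2 libraries, and log2 fold changes are IP minus input with their SE, computed from the fold change and the F statistic. The fit shares its estimate of spread across genes, so an SE can be smaller than the scatter of a gene's own libraries. Where 1 to 3 counts stood in a group, the ratio of pooled counts is given with its interval, and where a group had 0 counts, a bound from 3 counts over the group.

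Gene lists, 28 in number, were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 genes were tested, which held for 23 lists. Camera with an estimated correlation and fry stand beside it. The lists not tested for that reason were U2 snRNA genes, H/ACA box snoRNA, scaRNA, other small non-coding RNA and blood cell markers. Shares of counts by RNA class were compared with an exact permutation test, two-sided, whose smallest p with 2 against 2 libraries is 0.333. Exonic length is that implied by counts, FPKM and the recovered total, and intron length is the RefSeq span minus it. Single-exon and multi-exon genes, whose comparison was planned, were not compared, since these lengths do not tell them apart. Relations with gene span, intron length and exonic length are Spearman correlations across genes, which are not independent replicates. Other splits of the samples were not counted, since each group holds 2 libraries.

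The samples' groups, these tests, the gene lists, the rule for named genes and most other settings were fixed before the data were examined. The rule took SF3B6 itself; the 12 genes with the largest and the 12 with the smallest log2 fold change among genes past the threshold with mean CPM of at least 10 and both IP libraries beyond both inputs, without pseudogenes and clone names; and from each list the 2 most abundant members and up to 2 further members past the threshold. It took 87 tested genes. Of these, 55 are given by name, which does not include every gene that passed; the narrowing was made after values were seen. Those not named that did not pass had log2 fold changes from -1.12 to 0.98 and a smallest adjusted p of 0.113. WDR74 and some list members lie outside the rule and were chosen after their values were seen.

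Chosen after the data were seen were also the sums over gene copies of 18 small, ribosomal and mitochondrial RNA families, of which 17 were tested, and the use of the recovered FPKM totals as library sizes. Fixed in advance as other settings were RLE, upper quartile and total-count scaling, other filters, DESeq2 1.42.0, limma-voom, the FPKM table with pseudocounts of 1 and 0.1, a test against a 1.5-fold change, the replicate number as a block, the removal of mitochondrial and small non-coding genes, and the removal of each library in turn. Without 1 library its group holds a lone library, which is assumed to vary like the other group, so p-values of these fits rest on the spread of the other pair.

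EdgeR without and with the replicate block, limma-voom and DESeq2 were tested on simulated data with 200 changed genes drawn at the depths of these libraries (3647 genes tested). The test against a 1.5-fold change and limma-voom with the block were not. For the IP against input comparison, edgeR recovered 17.6% of genes raised 2-fold, 85.3% of those raised 4-fold and 100% of those raised 8-fold. For lowered genes the shares were 6.06%, 39.4% and 45.5%. It made 103 calls, 5 of them false, and 0 calls when no gene was changed. Camera at the preset correlation found a simulated 2-fold rise of ribosomal protein genes, which camera with the estimated correlation missed. Fry found it too, but called 4 lists when 1 had been raised. Simulated genes were drawn independently of each other. The simulation therefore does not show how camera at the preset correlation behaves where genes of a list vary together. The simulation used the common dispersion (0.00794) and so varied less than the real IP pair.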

Results

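RNA recovered with an SF3B6 antibody (IP) was set against input RNA in MDA-MB-231 cells, in 2 IP and 2 input libraries. Input was the one reference, so RNA recovered without regard to SF3B6 was not separated from RNA bound to it. SF3B6 is a small subunit of SF3b, the part of the U2 small nuclear ribonucleoprotein (snRNP) that holds the intron branch point, and the series asks which transcripts it contacts. Counts in genes came to 55492 and 30431 in the IP libraries and to 317190 and 519836 in the inputs. The IP libraries had counts in 9042 and 6334 genes and the inputs in 14509 and 15990. The 10 most abundant genes held 20.6% and 31.6% of IP counts, against 15.4% and 11.8% of input counts. Among the 3668 tested genes the median summed count was 8 over both IP libraries and 86 over both inputs, and 2220 genes had fewer than 10 IP counts. SF3B6's own transcript (chromosome 2, 24067586 to 24076326) had 0 counts in both IP libraries, and 0 and 1 in the inputs, so its recovery was not measurable at this depth.

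U2, U12 and 5S RNAs were among the RNAs higher in IP, and protein-coding transcripts made up those lower. In all, 99 genes were higher and 50 were lower in IP (edgeR, adjusted p under 0.05), of which 87 and 34 differed at least 2-fold. The lower genes were all protein-coding. The higher genes were 56 protein-coding genes and 43 others. By annotation the others included 11 snRNA, 9 lncRNA, 8 rRNA, 5 miRNA, 5 misc_RNA and 3 snoRNA genes. RNU11, the U11 snRNA gene, is annotated as lncRNA, as is RP11-596C23.6, with 5606 IP and 15710 input counts. Of the 56, 46 were nuclear, such as KIF1C (log2 fold change 1.72 ± 0.20 SE, edgeR adjusted p = 1.52e-07) and MUC1 (1.42 ± 0.24, 0.000118). Values of KIF1C and MUC1 in other settings are not reported here. Both IP libraries lay above both inputs in 97 of the 99 and below both in all 50, which a call at this number of libraries nearly requires. Among all 3668 tested genes, 799 lay above and 1005 below. Chance gives 33.3% for both directions together only where libraries are exchangeable. IP and input libraries differed in depth and spread, so no excess over chance is read from these numbers. The median log2 fold change of tested genes was -0.06 with TMM, -0.19 with upper quartile scaling, -0.31 with library totals and -1.65 with the totals recovered from the FPKM table. Higher genes made up 66.4% of calls with TMM, 49.3% with upper quartile scaling, 38.4% with library totals and 0.804% with the FPKM totals, which gave 17 higher and 2098 lower genes. DESeq2 called 35 and 3 genes, with no adjusted p for 1849. Fits without 1 library tested other numbers of genes: 6297 without SF3B6 IP 1, 1266 without input 1 and 1221 without input 2. Without SF3B6 IP 1, 30 and 15 genes were called, without input 1, 39 and 10, and without input 2, 26 and 5.

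U2 and U12 snRNA were the most enriched of the small RNA families. U2 pairs with the branch point of most introns, and U12 takes that place in the minor spliceosome, which removes a rare class of introns. Summed over 17 copies, U2 stood at 2536 ± 1359 CPM in IP against 232 ± 177 CPM in input (SD, n = 2 libraries each). That was 12.9-fold higher (log2 fold change 3.69 ± 0.26 SE, edgeR adjusted p = 1.14e-18). U12, the single gene RNU12 (chromosome 22, 42615244 to 42615393), was 20.8-fold higher at 738 ± 120 against 37.4 ± 9.81 CPM (log2 fold change 4.38 ± 0.34 SE, adjusted p = 1.02e-16). Both passed in every scaling tried and without each library in turn, where the spread of the lone library was taken from the other group. The size of the U2 change moved with single libraries, to 2.67 on the log2 scale without SF3B6 IP 1, 4.64 without input 1 and 2.89 without input 2, while U12 ran from 3.89 to 4.64. These shifts of U2 were each larger than its SE of 0.26, so that SE and its p understate the spread between libraries. With the FPKM totals their log2 fold changes were 2.03 and 2.71.

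Other spliceosomal RNAs varied. U4, which pairs with U6 before the spliceosome is activated, was 2.81-fold higher (log2 fold change 1.49 ± 0.19 SE, edgeR adjusted p = 2.82e-08), but its log2 fold change was -0.11 with the FPKM totals. U11, the minor spliceosome RNA that pairs with the start of the intron (RNU11, chromosome 1, 28648600 to 28648734), had 15 and 4 IP counts against 30 and 22 in input and was 4.14-fold higher (log2 fold change 2.05, adjusted p = 0.00950), but at 1.16 on the log2 scale without SF3B6 IP 1 and 1.38 without input 2. U11 did not pass with library totals (adjusted p = 0.0517), with the FPKM totals (0.578), with a replicate block (0.0570), or without SF3B6 IP 1 (0.647), input 1 (0.695) or input 2 (0.703). U1, which pairs with the start of most introns, had a log2 fold change of 0.00 ± 0.21 (adjusted p = 0.996) and U5 of 0.03 ± 0.30 (0.985). Both were negative with upper quartile scaling, library totals and the FPKM totals. With the last they were at -1.58 and -1.60, near the median of all tested genes at that scaling (-1.65). U4atac (0.73, adjusted p = 0.327) and U6atac (0.54, 0.807) did not pass, and U6 had too few counts to test. These family sums were chosen after the data had been seen.

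**Figure D1:**
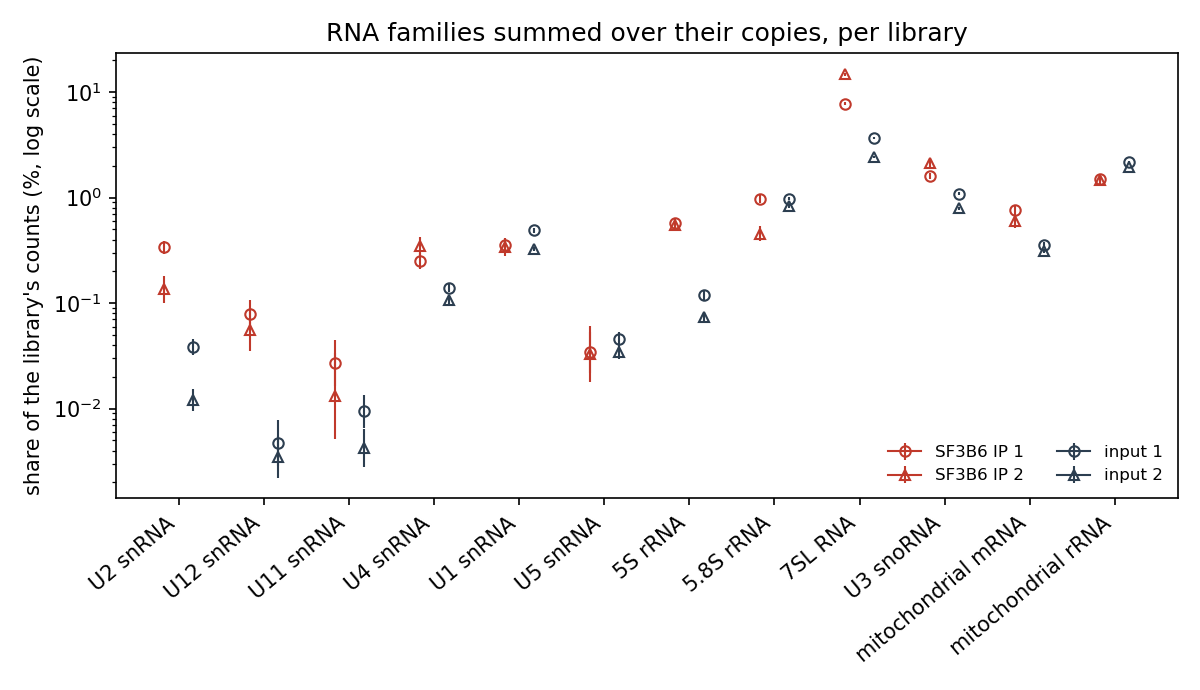
Share of each library's gene counts (%, log scale) held by 12 RNA families, summed over copies, for 2 SF3B6 IP and 2 input libraries; points are single libraries and bars are 95% Wilson intervals. U2 snRNA held 0.337% and 0.135% of the IP libraries and 0.0381% and 0.0121% of the inputs, whereas U1 snRNA shares of the groups overlapped.

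Single U2 and U4 genes were higher too. The table lists 12 genes named U2, on chromosome 17. Of these, 8 were tested and 7 were higher, with log2 fold changes from 2.94 to 5.40. Of these 7, the call held for 1 of the 2 still tested without SF3B6 IP 1, 6 of 6 without SF3B6 IP 2, 1 of 7 without input 1, 1 of 6 without input 2 and 6 of 7 with the FPKM totals. The other was at 0.23 (edgeR adjusted p = 0.967), with 3 and 1 counts in IP and 36 and 0 in input, and the copy at 2.94 had 14 and 6 in IP and 23 and 6 in input. The copy at 5.40 had 13 IP and 3 input counts, a 50.2-fold ratio with an interval from 13.8 to 274. RNU2-1 (chromosome 17, 43233790 to 43233977) rose by 2.88 ± 0.50 (edgeR adjusted p = 0.000201), with 41 and 1 counts in IP and 41 and 22 in input. Without SF3B6 IP 1 its log2 fold change was -1.11, and it was also negative on the log2(FPKM + 1) scale (-0.27). RNU4-2 (1.56 ± 0.21, adjusted p = 1.79e-06) and RNU4-1 (1.31 ± 0.22, 9.92e-05) rose, but with the FPKM totals were at -0.02 and -0.27. RNVU1-28, a variant U1 gene, was at 0.45 and did not pass (adjusted p = 0.294). How reads were shared among such copies is not known.

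Further small RNAs were enriched beside the snRNAs. 5S rRNA, the small RNA of the large ribosomal subunit, was 6.92-fold higher (log2 fold change 2.79 ± 0.20 SE, edgeR adjusted p = 6.37e-18), and 1.20 on the log2 scale with the FPKM totals. 7SL, the RNA of the signal recognition particle, was the most abundant family, at 126417 ± 64298 CPM in IP against 27736 ± 9202 CPM in input. Its log2 fold change was 2.14 ± 0.33 (adjusted p = 3.19e-06), but 0.49 with the FPKM totals (adjusted p = 0.133), and it did not pass without input 2 (0.156) or with a replicate block (0.0717). Without SF3B6 IP 2 it was at 1.44. The 7SL share rose as library depth fell, from 2.41% in input 2 and 3.65% in input 1 to 7.80% in SF3B6 IP 1 and 14.7% in SF3B6 IP 2. Shares of U3 and U4 had the same order, while those of U2, U12 and 5S were highest in SF3B6 IP 1. Both IP libraries were shallower than both inputs, so depth and IP cannot be told apart here. U3 snoRNA, which guides early cleavage of the ribosomal precursor, was 2.33-fold higher (adjusted p = 0.000812), yet at -0.40 with the FPKM totals, and did not pass without input 2 (0.382) or with a replicate block (0.0853). Most of its counts were those of SNORD3A, and the copies SNORD3B-1 and SNORD3B-2 did not rise (-0.34 and -0.04, adjusted p = 0.499 and 0.975; SNORD3B-2 at 0.11 without SF3B6 IP 2 and 0.18 without input 1). Among single genes, RNA5S7 (3.26 ± 0.48, adjusted p = 1.03e-05), RN7SL1 (2.22 ± 0.36, 6.66e-05), RN7SL3 (1.72 ± 0.23, 2.09e-06) and the U3 gene SNORD3A (1.34 ± 0.26, 0.000995) were higher. RNA5S7 did not pass without SF3B6 IP 1 (adjusted p = 0.126), input 1 (0.193) or input 2 (0.190), and RN7SL1, RN7SL3 and SNORD3A did not without input 2 (0.230, 0.0592 and 0.388). RN7SL1 and SNORD3A also did not with a replicate block (0.0729 and 0.0610). Without SF3B6 IP 2, RN7SL1 was at 1.42. With the FPKM totals RN7SL1 was at 0.58, RN7SL3 at 0.12 and SNORD3A at -0.27. A further 4 families of similar kind did not pass. 7SK, a regulator of transcript elongation, was at 0.05 (adjusted p = 0.951), 5.8S rRNA at -0.10 (0.913), RNase MRP RNA at -0.47 (0.245) and RNase P RNA at 0.44 (0.361). With the FPKM totals, which put the median of tested genes at -1.65, they were at -1.57, -1.67, -2.08 and -1.19. Without SF3B6 IP 1, 5.8S rRNA was lower (-0.93, adjusted p = 0.00297), and without SF3B6 IP 2 it was at 0.19 (0.699). The RNase P gene RPPH1 was at 0.43 (adjusted p = 0.411).

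MIR3648-1 and MIR3648-2, annotated as microRNA genes, were 3.18 ± 0.23 and 4.07 ± 0.24 higher on the log2 scale (edgeR adjusted p = 8.89e-13 and 7.72e-15). MIR3648-1 stood at 4304 ± 398 CPM in IP against 473 ± 236 CPM in input, and its log2 fold change was 3.82 without input 1. WDR74, which encodes a protein of ribosome assembly, was the protein-coding gene with the most counts among those at least 8-fold higher: 419 and 166 in IP against 324 and 448 in input. Its log2 fold change was 3.02 ± 0.21 (adjusted p = 2.79e-13). WDR74 (chromosome 11, 62832905 to 62841809) overlaps the U2 gene RNU2-2 (62841619 to 62841809) at the side of its higher coordinates. NOS2, the inducible nitric oxide synthase (chromosome 17, 27756766 to 27800529), had 23 and 3 IP counts against 0 and 3 in input, a 100-fold ratio of pooled counts with an interval from 30.8 to 518 (adjusted p = 1.85e-08). Without SF3B6 IP 1, which held 23 of these IP counts, NOS2 had too few counts to be tested. It did not pass without input 1 (adjusted p = 0.0608). Of the 12 highest genes by the rule, 12 passed with library totals and with the FPKM totals, as did the 8 that had a DESeq2 adjusted p. Calls held for 4 of the 5 still tested without SF3B6 IP 1, 10 of 10 without SF3B6 IP 2, 4 of 11 without input 1 and 5 of 10 without input 2. The calls lost were those of U2 copies, RNA5S7 and NOS2.

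Of 13 mitochondrial messenger RNAs, 10 were higher, while mitochondrial ribosomal RNA was not. MT-ND1 (0.49, edgeR adjusted p = 0.350; -0.11 without SF3B6 IP 1), MT-ND6 (0.93, 0.359) and MT-ND4L (-0.40, 0.749) did not pass. Summed over all 13, the messengers rose 2.41-fold (log2 fold change 1.27 ± 0.20 SE, edgeR adjusted p = 6.94e-06), with a value of -0.34 under the FPKM totals and no pass without input 2 (adjusted p = 0.144). The smallest adjusted p were those of MT-ND5 (2.18 ± 0.18, adjusted p = 3.85e-11) and MT-ND4 (1.81 ± 0.21, 1.07e-07), which encode subunits of complex I. With the FPKM totals they were at 0.56 and 0.20 and did not pass. MT-RNR1 and MT-RNR2, the mitochondrial rRNA genes, were at -0.37 and -0.12 (adjusted p = 0.443 and 0.884), and their sum at -0.23 (0.738), and at -1.85 with the FPKM totals, where the median of tested genes was -1.65.

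Transcripts lower in the IP libraries included some of matrix and secretory genes. FN1, which encodes fibronectin, fell by 1.63 ± 0.35 on the log2 scale (edgeR adjusted p = 0.00305). COL12A1, a collagen gene, fell by 1.60 ± 0.33 (0.00241), THBS1, thrombospondin, by 1.03 ± 0.22 (0.00319), CALR, an endoplasmic reticulum (ER) chaperone, by 1.12 ± 0.23 (0.00241) and SLC2A1, the GLUT1 glucose transporter, by 1.27 ± 0.27 (0.00302). CDH11, a cadherin (-2.16 ± 0.55, adjusted p = 0.0175), KIRREL1, an adhesion molecule (-1.80 ± 0.45, 0.0159), and MKI67, a proliferation marker (-1.25 ± 0.34, 0.0241), were also lower, MKI67 not with a replicate block (0.0502). Leaving out SF3B6 IP 1 ended the calls of FN1, SLC2A1, CDH11, KIRREL1 and MKI67 (adjusted p = 0.262, 0.0617, 0.230, 0.547 and 0.501). Leaving out input 2 ended those of the same 5 genes and of THBS1 (0.119, 0.0523, 0.294, 0.248, 0.230 and 0.116), and leaving out input 1 those of THBS1, CDH11, KIRREL1 and MKI67 (0.0768, 0.218, 0.111 and 0.141). CALR and COL12A1 passed without each library in turn, COL12A1 at -3.05 without SF3B6 IP 1. In the same way CDH11 was at -2.80 without SF3B6 IP 1 and KIRREL1 at -2.52 without SF3B6 IP 2. MAN2B1, a lysosomal mannosidase, and SRGAP2 had 0 IP counts against 87 and 84 in input, at least 2.5-fold and 2.42-fold lower (adjusted p = 0.0289 and 0.0343). Another 6 genes had 1 to 3 IP counts. MBTPS1 and RTN3 had 1 each, with ratios of 0.0877 (interval 0.00220 to 0.497) and 0.0905 (0.00227 to 0.513). ANXA11 had 2 (0.165, 0.0198 to 0.609), and MFGE8 (0.186, 0.0380 to 0.551), NUP210 and PTPRU (0.197, 0.0403 to 0.586 for both) had 3. Their adjusted p were 0.0221, 0.0260, 0.0405, 0.0386, 0.0205 and 0.0408. Of the 12 lowest genes by the rule, 12 passed with library totals, 7 with a replicate block (not SRGAP2, RTN3, ANXA11, MFGE8 and PTPRU), and 0 of the 7 that had a DESeq2 adjusted p. Calls held for 1 of 12 without SF3B6 IP 1, 9 of 12 without SF3B6 IP 2, 2 of 7 without input 1 and 1 of 6 without input 2.

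**Figure D2:**
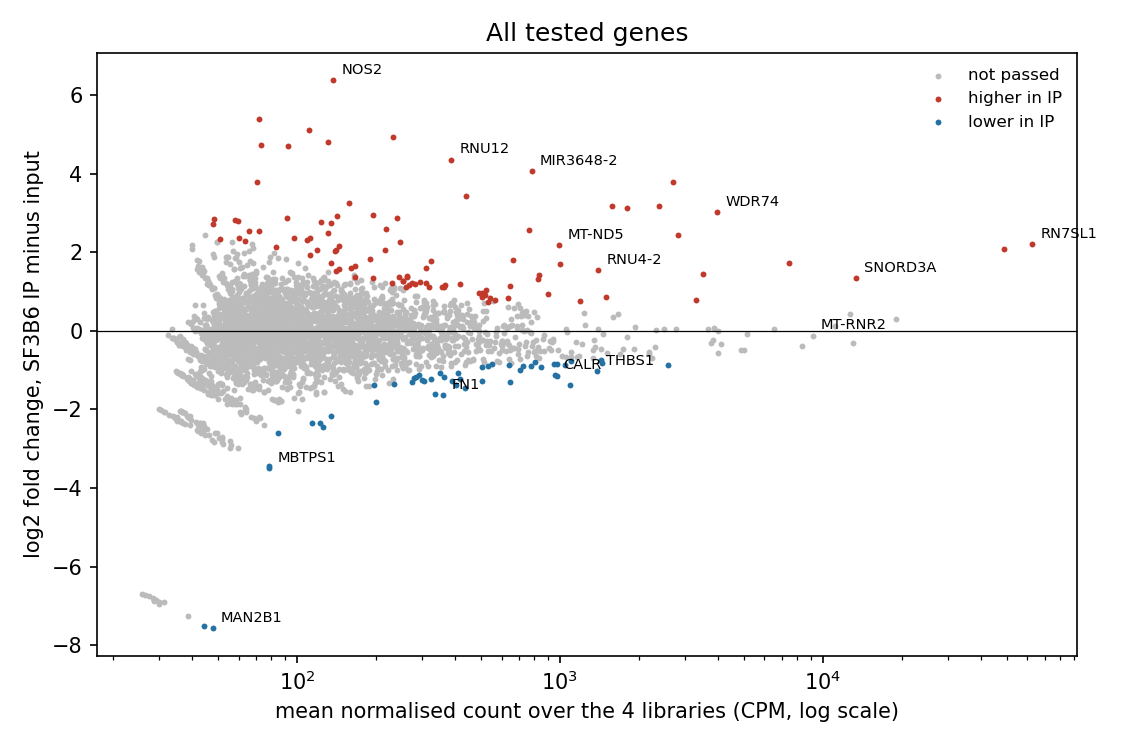
Log2 fold change of SF3B6 IP minus input against mean normalised count (CPM, log scale) for the 3668 tested genes; red points are the 99 higher and blue the 50 lower genes at edgeR adjusted p under 0.05. NOS2 lies highest at 6.38 and MT-RNR2 near 0 at -0.12, and the lowest points, set apart from the rest, are fitted values of genes with 0 IP counts and are not bounds.

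Of the 23 gene lists tested, 3 were higher and 2 were lower in IP by camera at a preset correlation. None passed with an estimated correlation (smallest adjusted p = 0.756, 0 at unadjusted p under 0.05). That test missed a simulated 2-fold rise, so its lack of calls does not argue against a list. For ER and secretory genes the estimated correlation was 0.0102, near the preset 0.01. Their unadjusted camera p was still 0.0770 against 0.000686, so the correlation itself does not account for that difference in this list. The other called lists had estimates above the preset. They were 0.724 for spliceosomal snRNA genes other than U2, 0.435 for mitochondrially encoded, 0.237 for C/D box snoRNA and 0.126 for matrix genes. At the preset correlation the camera p of these lists may therefore be too small. Fry, which did find the simulated rise, called 0 one way, with 3 at unadjusted p under 0.05, and 7 in either direction. Mitochondrially encoded genes had a median log2 fold change of 0.97 over 17 genes (adjusted p = 8.96e-11); 10 rose, all of them messengers, over all genes tested and adjusted over the list alone. Spliceosomal snRNA genes other than U2 had a median of 0.49 over 17 genes (adjusted p = 5.58e-05), of which 4 rose by either count. The snRNA list did not pass without input 2 (adjusted p = 0.393), with a minimum of 50 counts in 2 libraries (0.0671) or with no filter (0.0861), and the mitochondrial list did not with no filter (0.292). C/D box snoRNA genes, which guide RNA methylation or processing, had a median of -0.03 and a mean of 0.35 over 7 genes (adjusted p = 0.0295). The 3 that rose, SNORD3A, SNORD3C (1.24, edgeR adjusted p = 0.0261) and SNORD17 (0.80, 0.0468), include 2 of the 4 U3 genes, and all 3 were below 0 with the FPKM totals. SNORD3C did not pass without SF3B6 IP 1 (0.609) or input 2 (0.424), nor SNORD17 without SF3B6 IP 2 (0.886, log2 fold change 0.085), input 1 (0.115) or input 2 (0.486), nor SNORD3A without input 2 (0.388). With a replicate block none of the 3 passed (0.0610, 0.0607 and 0.175 in the order named). That list did not pass with RLE, upper quartile or total-count scaling (adjusted p = 0.0656, 0.0637 and 0.202), with a replicate block (0.180) or with a minimum of 50 counts in 2 libraries (0.0821), nor without SF3B6 IP 2 (0.142), input 1 (0.189) or input 2 (0.706).

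The mesenchymal and matrix list had a median of -0.40 over 23 genes (camera adjusted p = 0.000169); FN1 and THBS1 fell, and 4 genes were lower adjusted over the list alone. Its most abundant members, ITGA3 (-0.30, edgeR adjusted p = 0.508) and AXL (-0.57, 0.118), did not pass. ER chaperones and secretory genes had a median of -0.62 over 16 genes (camera adjusted p = 0.00394); CALR fell, and 6 genes were lower adjusted over the list alone. P4HB, a protein disulfide isomerase, was at -0.67 (edgeR adjusted p = 0.0745). This list did not pass without SF3B6 IP 1 (camera adjusted p = 0.0751), nor the matrix list with a minimum of 50 counts in 2 libraries (0.0821). With an estimated correlation both lists had adjusted p = 0.756.

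**Figure D3:**
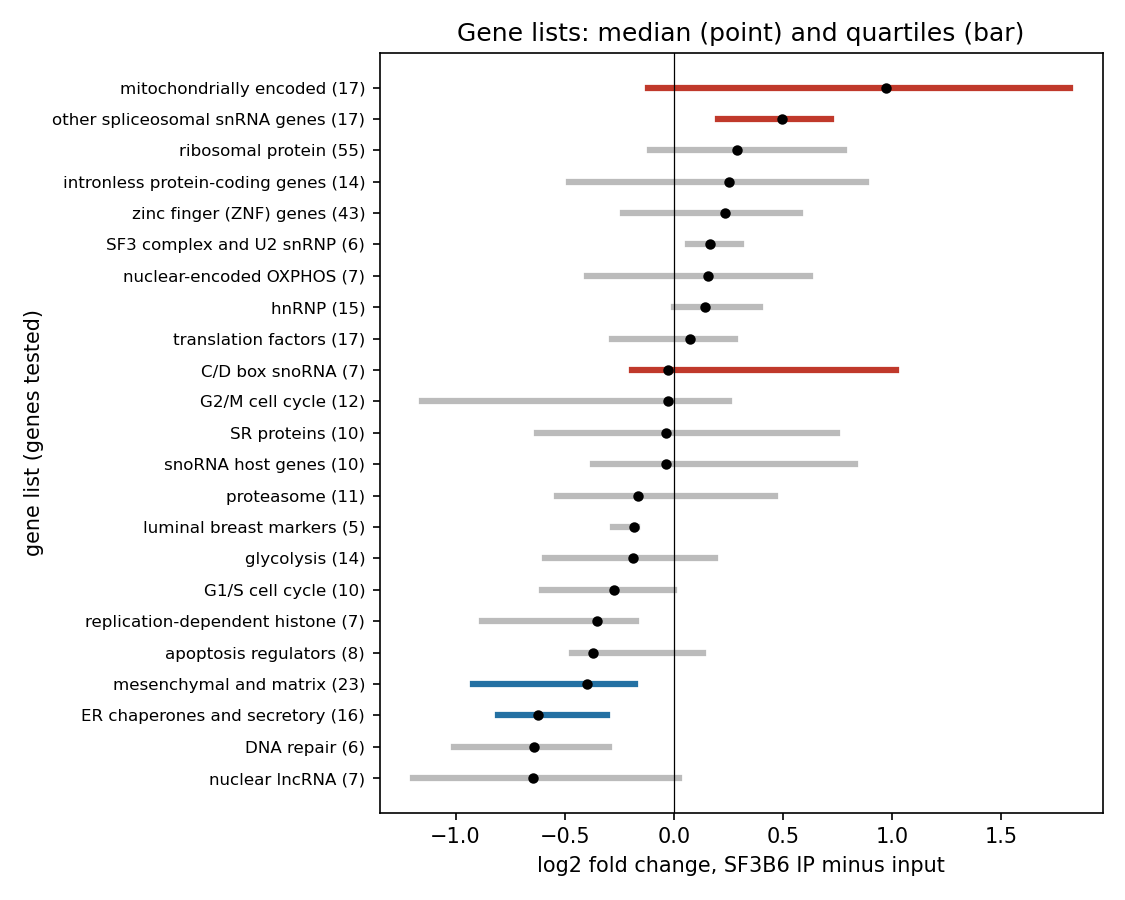
Median (point) and quartiles (bar) of the log2 fold change of SF3B6 IP minus input for 23 gene lists, with the number of genes tested; red lists were higher and blue lists lower by camera at a preset correlation. Medians ran from -0.65 for nuclear lncRNA to 0.97 for mitochondrially encoded genes, and C/D box snoRNA was called higher at a median of -0.03. None of the 23 passed with an estimated correlation, a test that also missed a simulated 2-fold rise.

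The other 18 lists did not pass camera. Ribosomal protein genes had a median of 0.29 over 55 genes (adjusted p = 0.0995), with RPL36 higher (1.60, edgeR adjusted p = 0.0334), a call lost with upper quartile scaling and library totals and without any 1 library (0.228, 0.254, 0.562 and 0.645), and with a replicate block (0.0736). Genes of the SF3 complex and U2 snRNP had a median of 0.17 over 6 genes (camera adjusted p = 0.838); SF3B2 was at 0.35 and U2AF2 at 0.15 (edgeR adjusted p = 0.818 and 0.915). Medians were -0.04 for SR proteins (camera adjusted p = 0.844), with SRRM2 at -0.25 and SON at -0.16, and 0.14 for hnRNP (0.558). For nuclear lncRNA the median was -0.65 (adjusted p = 0.542), and MALAT1 and NEAT1, the most abundant, were at 0.00 and 0.05. SnoRNA host genes had a median of -0.04 (adjusted p = 0.469), with SNHG1 higher (1.03, edgeR adjusted p = 0.00971), although at -0.54 with the FPKM totals and not past the threshold with library totals (0.0772) or without SF3B6 IP 2 (0.283) or input 2 (0.169). Zinc finger genes had a median of 0.24 (camera adjusted p = 0.400), with ZNF653 higher (2.72, edgeR adjusted p = 0.0334) but not with upper quartile scaling (0.0539) or library totals (0.0587). Glycolysis genes had a median of -0.19 (camera adjusted p = 0.422), with SLC2A1 lower and PKM and ENO1 at -0.67 and -0.71 (edgeR adjusted p = 0.0739 and 0.0854). The rest lay between -0.64 and 0.25: DNA repair -0.64 (camera adjusted p = 0.469), apoptosis regulators -0.37 (0.838), histones -0.35 (0.554), G1/S -0.28 (0.792), luminal breast markers -0.18 (0.469), proteasome -0.17 (0.890), G2/M -0.03 (0.636), translation factors 0.08 (0.798), nuclear-encoded respiratory chain 0.16 (0.849) and intronless genes 0.25 (0.551). Among lists with fewer than 5 tested genes, medians were -0.38 for 4 H/ACA box snoRNA genes, -0.76 for 3 scaRNA genes and 1.08 for 4 other small non-coding RNA genes, of which RN7SL1 and RN7SL3 rose. In the last of these 1 gene was lower adjusted over the list alone. Of the U2 list RNU2-1 alone was tested, and of the blood cell markers 1 gene, at 0.099.

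As shares of all counts, small non-coding RNAs other than snRNA and snoRNA, mainly 7SL, took 13.6% ± 5.22 of IP and 5.56% ± 1.24 of input libraries (SD, n = 2 each). Spliceosomal and related snRNAs took 1.04% ± 0.118 against 0.633% ± 0.173, and snoRNA and scaRNA 2.39% ± 0.553 against 1.40% ± 0.246. Mitochondrially encoded genes took 2.19% ± 0.150 and 2.42% ± 0.201. The smallest p an exact permutation test of 2 against 2 libraries allows is 0.333, which the first 3 classes reached (0.533 after adjustment over 8 classes). Over summed FPKM, the differences for snRNA and for snoRNA and scaRNA were of opposite sign, at -0.330 and -1.03 percentage points.

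Longer genes had slightly lower gene counts in IP relative to input. Reads outside the listed genes do not enter these counts, so recovery of whole transcripts was not measured. Across 3407 protein-coding genes the Spearman correlation of log2 fold change with gene span was -0.19, and with intron length also -0.19. With exonic length it was -0.13 and with mean expression -0.17, across 3483 genes. In 5 groups of equal size ordered from short to long span, the medians were 0.08, 0.04, -0.08, -0.18 and -0.26. Without SF3B6 IP 1 the correlation with span was -0.055, and for SF3B6 IP 2 against input 2 it was -0.074. These are relations across genes, with no test of replicates.

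Between libraries, log2 CPM across the tested genes correlated at a Pearson r of 0.598 for the IP pair and 0.960 for the input pair, and at 0.637 to 0.730 between IP and input. Among 205 genes with a mean of at least 500 CPM, a limit set after the data were seen, the IP pair correlated at 0.932 and IP with input at 0.692 to 0.775.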

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

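All tests in this part except those of the 2 gene lists were chosen after the result was seen. Outlier tests need groups of at least 4 libraries and were not possible here.

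A larger part of the FPKM totals lay outside the listed genes in the IP libraries than in the inputs. What that total counts is not given in the sources used here, and it was recovered from 14, 9, 36 and 40 genes of the 4 libraries. The library totals recovered from the FPKM table placed 93.3% ± 0.885 of the IP total and 82.3% ± 3.86 of the input total (SD, n = 2 each) outside the listed genes, a part of the data that the comparison of genes does not use. Mature ribosomal RNA, of which 18S and 28S were not analysed here, was tested through 5.8S and 5S, parts of the same large subunit as 28S. Relative to the FPKM totals, which put the median of tested genes at -1.65, 5.8S was at -1.67 ± 0.37 (SE) and 5S at 1.20 ± 0.42, so that they moved apart and ribosomal RNA as the filling stays open. A minimum count for listing a gene is argued against, since the lowest summed count of a listed gene was 1. Intronic, intergenic and ribosomal precursor reads may also fill this part, as may binding of introns by SF3B6, and none of these was tested.

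WDR74 was 3.02 higher on the log2 scale, although it is a messenger RNA. A trend of enrichment with gene length and abundance is argued against, because the 100 protein-coding genes closest in span, exonic length and abundance had a median of -0.21, with an SD of 0.56 over genes. U2 reads from RNU2-2, which lies within WDR74 at the side of its higher coordinates, may have been counted for it. WDR74 minus the summed U2 genes was -0.65 ± 0.32 (SE), and without 1 library it ran from -1.38 (input 1) to 0.025 (input 2), at -0.053 without SF3B6 IP 1. Values at or below 0 are possible for diluted U2 reads and for bound messenger, so both stay open: one count per gene cannot separate them. Binding of the messenger by SF3B6 was not tested.

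Matrix genes and ER and secretory genes were lower as lists by camera at a preset correlation, with medians of -0.40 and -0.62. Neither passed with an estimated correlation (adjusted p = 0.756 for both) or by fry (0.280 and 0.277), nor the ER and secretory list without SF3B6 IP 1 (0.0751) or the matrix list with at least 50 counts in 2 libraries (0.0821). Random lists matched on span, exonic length and abundance had medians as low in 15.7% and 0.48% of 10000 draws, around random medians of -0.23 and -0.10. The length and abundance trend could therefore account for the matrix list, while matched genes were rarely as low as the ER and secretory list. The draws take genes as independent and the fold changes as fixed. They do not cover the spread between libraries, so a cause for the ER and secretory list is not settled. GC content was not tested here. A lower contact of SF3B6 with these transcripts stays open as a hypothesis.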

How the results depend on the processing

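The FPKM totals, the summed families with all their alternatives and the 500 CPM limit were chosen after the data were seen; the other tests were planned. Replicate numbers were not taken to pair samples, since no shared batch is stated. The correlation of deviations was 0.000443 over 2 pairs, which at these low IP counts cannot exclude a pairing. With replicate numbers as a block, edgeR called 68 higher and 22 lower genes, limma-voom with the block 166 and 47, and camera 2 and 2 lists. IP counts were low, with 2220 of 3668 tested genes under 10. In the simulation at these depths edgeR recovered 17.6% of genes raised 2-fold and 6.06% of those lowered 2-fold.

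Higher and lower genes, 99 and 50, became 116 and 53 with RLE and 67 and 69 with upper quartile scaling. They were 56 and 90 with library totals, 50 and 163 with no filter, 80 and 25 with at least 50 counts in 2 libraries, 35 and 3 with DESeq2 (1849 adjusted p not given), 201 and 74 with limma-voom and 49 and 1 against a 1.5-fold change. Counts were 25 and 2548 on log2(FPKM + 1), 25 and 1865 on log2(FPKM + 0.1), and 17 and 2098 with FPKM totals. On log2(FPKM + 1) without a filter limma called 0 and 0, with 59 and 5384 at unadjusted p under 0.05. Leaving out 1 library gave 26 to 94 and 5 to 70. Genes tested were 6297 and 6213 without SF3B6 IP 1 and 2 and 1266 and 1221 without input 1 and 2. They were 18276 with no filter and 1115 with at least 50 counts, against 3668. Of the 99 and 50 genes, 86 to 94 and 44 to 50 were still tested with 1 library left out. With families summed, 73 and 51 genes were called, and without mitochondrial and small non-coding genes 70 and 64. Lists higher and lower, 3 and 2, were 0 and 0 with estimated correlation or fry, 3 and 11 with no filter, 1 and 1 with at least 50 counts, 0 and 2 without small non-coding and mitochondrial genes, which make up the 3 higher lists, and 1 to 4 and 1 to 2 with 1 library left out. Other scalings gave 2 and 2. Lists tested were 28 with no filter, 10 with at least 50 counts or without an input and 25 without an IP library, against 23.

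Differences in class share over summed FPKM were -2.19 (mitochondrial), -0.330 (snRNA), -1.03 (snoRNA and scaRNA) and 14.0 (other small non-coding) percentage points, against -0.222, 0.407, 0.987 and 8.06 over counts. The correlation with span was -0.074 for IP 2 against input 2 and -0.23 to -0.055 with 1 library left out. The IP pair correlated at 0.932 at 500 CPM or more and 0.892 on log2(FPKM + 1); a limit of 10 CPM removed no gene and tests nothing.

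Values of opposite sign follow; apart from what the setting itself does, the cause was not tested. Log2(FPKM + 1), with or without filter, and log2(FPKM + 0.1) gave RNU2-1 -0.27 and -0.31, RNU4-1 -0.26 and -0.26, RNU4-2 -0.022 and -0.022, SNHG1 -0.49 and -0.52, SNORD17 -0.86 and -0.86, SNORD3A -0.27 and -0.27, SNORD3C -0.45 and -0.45, MT-ND6 -0.66 and -0.69, MT-ND1 -1.22 and -1.25. In that order, MALAT1 had -1.59 and -1.62, NEAT1 -1.48 and -1.55, RNVU1-28 -1.12 and -1.13, RPPH1 -1.19 and -1.20, SF3B2 -0.74 and -1.20, and U2AF2 -1.27 and -1.52. FPKM totals gave RNU4-1 -0.27, RNU4-2 -0.022, SNHG1 -0.54, SNORD17 -0.83, SNORD3A -0.27, SNORD3C -0.40, MT-ND6 -0.68, MT-ND1 -1.14, MALAT1 -1.61, NEAT1 -1.58, RNVU1-28 -1.13, RPPH1 -1.19, SF3B2 -1.25 and U2AF2 -1.46, and the sums of U1 -1.58, U5 -1.60, U4 -0.11, U3 -0.40, 7SK -1.57 and mitochondrial mRNA -0.34. No filter gave MALAT1 -0.48, NEAT1 -0.45, RNVU1-28 -0.034, RPPH1 -0.090, SF3B2 -0.12 and U2AF2 -0.32. Upper quartile scaling and library totals gave MALAT1 -0.13 and -0.25, NEAT1 -0.090 and -0.21, U1 -0.069 and -0.26, U5 -0.030 and -0.25, 7SK -0.026 and -0.22, and totals U2AF2 -0.092. The edgeR replicate block gave U5 -0.072 and MALAT1 -0.0081, and limma-voom with the block MALAT1 -0.00091. At least 50 counts gave MT-RNR2 0.10, SON 0.047 and SNORD3B-2 0.16. With 1 library left out, ranges were RNU2-1 -1.11 to 3.65, MT-ND1 -0.11 to 0.61, MT-RNR2 -0.31 to 0.057, SON -0.53 to 0.048, SNORD3B-2 -0.95 to 0.18, U2AF2 -0.49 to 0.28, NEAT1 -0.13 to 0.11, SF3B2 -0.29 to 0.43, MALAT1 -0.33 to 0.077, U1 -0.24 to 0.45, U5 -0.21 to 0.31, 5.8S -0.93 to 0.19 and 7SK -0.19 to 0.32.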

Other observations

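The tests in this part were chosen after the data were seen. MIR3648-1 (chromosome 21, 8208473 to 8208652), one of the 12 highest genes in IP, lies inside RNA45SN2 (8205988 to 8219302), a gene of the ribosomal RNA precursor, ahead of the start of 18S rRNA at 8209631. Its position is that of the external spacer, which is removed from the precursor. Where its reads lie was not tested.

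By chromosome, 46 of 3470 tested nuclear protein-coding genes were higher in IP. Chromosome 19 held 10 of them among 374 tested genes and chromosome 16 held 6 among 176 (Fisher's exact p = 0.0270 and 0.0271). Over 23 chromosomes both had an adjusted p of 0.311, so neither passed.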
